A study of Mus musculus with 11 samples.

How the data were processed

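RNA of eosinophils sorted from mouse blood was sequenced after Smart-seq2 library preparation in 11 libraries, 7 from mice given cisplatin, anti-PD1 and anti-CTLA4 and 4 from mice given control antibody, per the labels. The authors deposited raw counts per Ensembl gene in 1 table. Per the submitters' processing notes, bcl2fastq 2.20.0.422, HISAT2 2.10 and SAMtools 1.15.1 were used with the genome build GRCm38. The read counter, the strand setting and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes, of gene copies and of pseudogenes may have been split or shared. The table had 55486 genes and 1 row that names no gene, which held 0 counts and was left out. Of these genes, 55226 matched the GENCODE M21 annotation by identifier. Library totals ran from 3733156 to 8016658 counts, and reads had no molecular identifiers, so intervals cover counting error only. No pair of libraries was a duplicate (chi-square per gene 59.2 or more).

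Groups were taken from the treatment label. Counts were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test with robust dispersions, TMM scaling, the filter filterByExpr and Benjamini-Hochberg adjustment over 11389 genes at a threshold of 0.05. Fold changes are treated minus control on the log2 scale. Printed CPM of single genes are scaled with TMM, and summed marker levels are CPM of the library total. Gene lists with at least 5 tested members (29 of 22 functional and 11 marker lists) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry. Marker levels, as log2 of the summed CPM with a pseudocount of 1, and 4 library quality measures were compared by exact two-sided permutation over the 330 splits of the libraries. The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule named the 12 genes with the largest change in each direction among those past the threshold, which were none, up to 2 members with the highest mean CPM of each list, a fixed set of sort markers and antibody targets, and, since fewer than 10 genes passed, the 10 genes with the smallest p-values at a mean of 10 CPM or more in a group. The choice by mean CPM used CPM of the library total.

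The test was checked on simulated counts drawn from the means and library sizes of these libraries, with 50 of the more abundant genes changed at each of 4 fold changes. It recovered 4 genes at a log2 change of 1, 30 at 2, 42 at 3 and 49 at 4, and called 7 unchanged genes. In the same simulation 22 genes of the interferon gamma list were raised by 1 on the log2 scale, and these are in none of the counts. Alternatives fixed in advance were DESeq2 size factors, upper-quartile scaling, DESeq2 1.42.0, limma-voom with quality weights, other filters, a replicate block, detected genes as a covariate, a fold minimum, a threshold of 0.1 and leaving out each library. Alternatives chosen after seeing the data were leaving out control 3 and control 4 together, removing erythroid and platelet genes, an offset for transcript length and GC content, marker levels or the letters of the sample identifiers as covariates, an estimated correlation in each of the other edgeR settings, and exact permutation of list scores. A list score is the mean log2 CPM of the tested members per library. The marker levels used as covariates were these list scores of the marker lists, not the summed CPM. Because the libraries with few detected genes had lower log2 CPM for most genes, a second form was added in which each member was set against the genes of the same mean expression, in 40 bins, in the same library. With the length and GC offset, lists were tested with preranked camera, which takes 1 statistic per gene from the quasi-likelihood test, at the same preset correlation. List p-values with this correction thus come from another test, and a call gained or lost there can also reflect that change. Python 3.11.15 with scipy 1.17.1 was used for permutation tests.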

Results

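Gene expression was measured by Smart-seq2, a full-length RNA-seq protocol for small amounts of RNA, in eosinophils sorted from the blood of FVB/N mice with metastatic disease from mammary tumours. Blood was taken by heart puncture on day 21 after the start of treatment, and eosinophils were gated as live CD45+ CD3- CD11b+ F4/80+ cells with low Ly6g and high side scatter. In 7 mice the treatment was cisplatin, a DNA-crosslinking drug, together with antibodies against the checkpoint receptors PD1 and CTLA4. The other 4 mice received control antibody. Each library came from a different mouse. The total count per library was 5356118 to 8016658 in the treated group and 3733156 to 6721060 in the control group.

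The sorted cells carried eosinophil transcripts in every library. Siglecf, a sialic acid receptor of eosinophils, stood at 493 ± 182 counts per 1000000 (CPM; SD, n = 7) in treated and 592 ± 336 (SD, n = 4) in control libraries. Ccr3, the eotaxin receptor, stood at 2820 ± 1240 and 3210 ± 1120 CPM, and Il5ra, a subunit of the IL-5 receptor, at 196 ± 76.6 and 223 ± 164 CPM. Adgre1, which encodes F4/80, stood at 1470 ± 639 and 1450 ± 656 CPM, and Itgam, which encodes CD11b, at 441 ± 109 and 321 ± 63.1 CPM. The granule genes Prg2 (344 ± 243 and 759 ± 1060 CPM) and Epx (40.7 ± 37.1 and 46.0 ± 52.9 CPM) varied widely between libraries. Without control 3 and control 4 the log2 fold change of Il5ra went from -0.188 to -0.824, that of Prg2 from -1.14 to 0.0176 and that of Epx from -0.169 to 0.932. Prg2 stood at 659, 33.2, 2290 and 54.5 CPM in control 1 to control 4. None of these genes passed the test between groups (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p from 0.749 for Itgam to 0.997 for Adgre1). Of the CD3 chains, Cd3e had 0 counts in all control libraries and 0.847 ± 1.04 CPM in treated ones, while Cd3d was detected in all 11 libraries, at 13.5 ± 6.15 CPM in treated and 20 ± 12 CPM in control libraries. Ly6g was detected in 1 treated and 2 control libraries.

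Library quality differed most within the control group. In control 3 and control 4 the 4 haemoglobin genes took 28.2% (95% Wilson interval 28.1 to 28.2) and 20.1% (20.1 to 20.2) of counts, against 1.06% (1.05 to 1.07) in control 1, 0.165% (0.162 to 0.168) in control 2 and 1.16% to 4.42% in the treated libraries. These intervals cover counting error only. Control 3 and control 4 also had the fewest detected genes (10775 and 11263, against 12639 or more elsewhere) and the highest share of counts on the 50 most abundant genes (49.6% and 44.1%). Mitochondrially encoded genes took 1.61% ± 0.636 (SD, n = 7) of counts in treated and 2.90% ± 0.800 (SD, n = 4) in control libraries (exact two-sided permutation test, p = 0.0182, adjusted p = 0.0727 over 4 measures). Total count, detected genes and the share of the top 50 genes had adjusted p = 0.0939 each by the same exact permutation test. The sample identifiers in the header of the count table begin with 19 for all treated and 20 for all control libraries. If these digits mark a batch, it cannot be told apart from the treatment, because each batch would hold 1 group only. The letters that follow are KDV for treated 1 and all controls and VIS for treated 2 to treated 7, a second possible grouping. With the letters as a covariate the treatment term rests on treated 1 against the controls, and 0 genes passed. In that fit, by camera with the preset correlation, MHC class II presentation and B cell markers turned to lower, and glycolysis to higher. The calls of type 2 activation, immediate early and heat shock genes, monocyte and macrophage markers and platelet markers ended. These shifts rest on 1 treated library, and no list was called there with an estimated correlation.

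**Figure D1:**
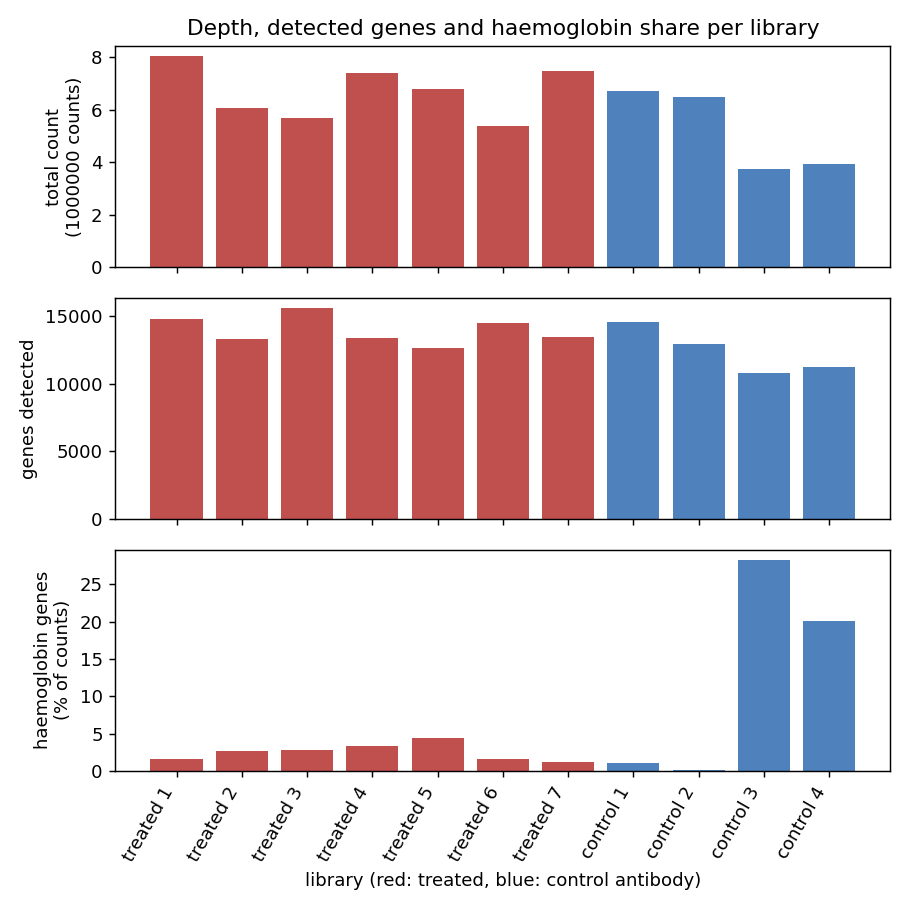
Total count, in units of 1000000 counts (top), number of genes with at least 1 count (middle) and share of counts on 4 haemoglobin genes in percent (bottom) for each of the 11 libraries, with 1 bar per library, red for treated and blue for control antibody. Control 3 and control 4 have the lowest totals, the fewest detected genes and haemoglobin shares of 28.2% and 20.1%.

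The comparison asked how the combination of cisplatin, anti-PD1 and anti-CTLA4 altered gene expression of blood eosinophils relative to control antibody. No single gene passed the edgeR test in either direction, while DESeq2 called 60 genes higher and 22 lower. The genes with the smallest p-values included Gpx4, a glutathione peroxidase that reduces lipid peroxides, at 242 ± 45.5 CPM in treated (SD, n = 7) and 566 ± 197 CPM in control libraries (SD, n = 4), and Tmpo, a nuclear envelope protein, at 125 ± 28.0 and 50.2 ± 12.5 CPM. As groups, genes of mitochondrial respiration had lower values in treated libraries, and genes of MHC class II presentation and interferon gamma response had higher values, but none of these list calls held with an estimated correlation between genes.

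Of 11389 genes tested with edgeR, 0 were higher and 0 lower at an adjusted p of 0.05, and 777 had an unadjusted p under 0.05. The smallest adjusted p was 0.355. DESeq2 called 60 genes higher and 22 lower, of which 19 of the higher ones had 0 counts in all 4 control libraries. Of all its calls, 73 passed the filter used for edgeR and 32 were detected in all 11 libraries. Biological variation was high, with a common coefficient of variation of 0.828. On simulated data with the spread of these libraries, edgeR recovered 8% of genes changed by 1 on the log2 scale, 60% of those changed by 2 and 98% of those changed by 4. The changed genes counted here were drawn from the more abundant genes only, so these rates do not cover genes of low abundance.

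The 10 genes with the smallest p-values and at least 10 CPM in a group did not pass the edgeR test. DESeq2 called all 10 of them, with adjusted p from 7.06e-08 for Aldh1b1 to 0.0325 for H1f2. Gpx4 (chromosome 10, 80047166 to 80056439, GRCm38) had a log2 fold change of -1.23 ± 0.236 (SE; adjusted p = 0.355, edgeR), or -0.711 without control 3 and control 4, and Tmpo (chromosome 10, 91147571 to 91181315) one of 1.32 ± 0.259 (adjusted p = 0.355, edgeR). St8sia4, a polysialyltransferase, stood at 121 ± 33.0 CPM in treated and 48.5 ± 17.9 CPM in control libraries. Gpx3, a secreted glutathione peroxidase, had 0 counts in all control libraries and 10.2 ± 7.70 CPM in the treated group, at least 68.9-fold higher than the floor of 3 counts over the control group. Aldh1b1, a mitochondrial aldehyde dehydrogenase, stood at 11.1 ± 3.01 against 0.127 ± 0.254 CPM. Slamf9 (32.5 ± 28.7 against 0.436 ± 0.781 CPM), Thnsl1 (12.8 ± 11.2 against 0.0317 ± 0.0634 CPM) and Slfn9 (9.78 ± 8.35 against 0.0354 ± 0.0707 CPM) were close to absent from control libraries. H1f2, a linker histone, stood at 72.4 ± 27.9 CPM in treated and 273 ± 208 CPM in control libraries, and Prpf39, a splicing factor, at 37.6 ± 8.17 and 94.3 ± 54.5 CPM. The high mean of H1f2 came from control 3 (494 CPM) and control 4 (406 CPM), without which its log2 fold change went from -1.91 to -0.375.

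Of the antibody targets, Pdcd1 had 0 counts in all 11 libraries. Ctla4 had 0 counts in all control libraries and counts in 2 of 7 treated libraries. Cd274, which encodes the PD1 ligand PD-L1, stood at 57.7 ± 31.2 CPM in treated (SD, n = 7) and 41.2 ± 19.1 CPM in control libraries (SD, n = 4; adjusted p = 0.926, edgeR).

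Genes of mitochondrial respiration fell as lists by camera with a preset correlation of 0.01. All 7 tested mitochondrially encoded genes were lower adjusted over the list alone, and 0 over all genes (median log2 fold change -1.07, adjusted p = 1.24e-10, and adjusted p = 0.404 with an estimated correlation). In mt-Cytb, of complex III, the level was 4110 ± 1670 CPM in treated (SD, n = 7) and 8950 ± 2860 CPM in control libraries (SD, n = 4), and in mt-Co1, of complex IV, 2370 ± 1000 and 5010 ± 2550 CPM. The highest of these were control 3 and control 4, in which mt-Co1 stood at 6689 and 7637 CPM, against 3295 and 2399 CPM in control 1 and control 2. Without them the log2 fold change of mt-Co1 went from -1.08 to -0.233, that of mt-Cytb from -1.12 to -0.722 and the median of the list from -1.07 to -0.441 (adjusted p = 0.0134 by the preset test, adjusted p = 0.471 with an estimated correlation, and exact permutation p = 0.278 for the list score). Of 35 nuclear genes of oxidative phosphorylation, 30 had a fold change below 0 and 0 passed adjusted over the list alone (median -0.42, adjusted p = 2.49e-10, and adjusted p = 0.419 with an estimated correlation). Its 2 most abundant members did not show this size of difference, with Atp5b at 532 ± 87.9 and 599 ± 123 CPM and Uqcrc1 at 452 ± 98.5 and 411 ± 111 CPM. Fold changes rose with transcript length across 7788 genes (Spearman rho 0.284, genes not being independent replicates), and a correction for length and GC content took the median of the nuclear list relative to all genes from -0.45 to -0.21. Reads of mitochondrial genes can be shared with nuclear copies, so these levels are uncertain to that degree.

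Cytosolic ribosomal proteins fell by the preset test (45 of 52 members with a fold change below 0, median -0.20, adjusted p = 0.000102), and not with an estimated correlation (adjusted p = 0.672 with an estimated correlation). With the correction for length and GC content the adjusted p was 0.438 by preranked camera, the test used for lists wherever this correction was made. Without control 3 and control 4 it was 0.480 by the preset test, and without control 3 alone 0.0520. Rps9 stood at 589 ± 75.8 CPM in treated (SD, n = 7) and 776 ± 284 CPM in control libraries (SD, n = 4). Glycolysis genes also fell by the preset test (13 of 19 below 0, adjusted p = 0.0425, and adjusted p = 0.559 with an estimated correlation). The glycolysis call ended without any 1 of control 1, control 3, control 4, treated 2, treated 3 or treated 5 (adjusted p from 0.0533 to 0.194). It also ended without control 3 and control 4 together (0.231), without erythroid and platelet genes (0.0515) and with detected genes (0.0850) or the B cell marker level (0.266) as a covariate. The most abundant member, Aldoa, stood at 1780 ± 427 and 2040 ± 421 CPM.

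MHC class II presentation rose by the preset test, with 10 of 11 members above 0 (median log2 fold change 1.51, adjusted p = 0.000157, and adjusted p = 0.506 with an estimated correlation). The invariant chain Cd74 stood at 3440 ± 2280 CPM in treated (SD, n = 7) and 1150 ± 541 CPM in control libraries (SD, n = 4), and H2-Ab1 at 1960 ± 1310 and 685 ± 366 CPM. Interferon gamma response genes rose by the same test (22 of 23 above 0, median 0.82, adjusted p = 0.00127, and adjusted p = 0.559 with an estimated correlation), while Irf1 stood at 189 ± 75.4 and 181 ± 59.6 CPM. Markers of B cells (12 of 14 above 0, adjusted p = 0.0116, and adjusted p = 0.650 with an estimated correlation) and of monocytes and macrophages (11 of 15 above 0, adjusted p = 0.0401, and adjusted p = 0.672 with an estimated correlation) moved in the same direction. Ighm, the immunoglobulin mu chain, stood at 1890 ± 750 and 1150 ± 402 CPM, while Bank1, also among the most abundant B cell markers, stood at 283 ± 80.7 and 309 ± 165 CPM. Of the monocyte and macrophage markers, Lyz2 stood at 4560 ± 3090 and 4620 ± 6800 CPM and Ctss at 1150 ± 902 and 724 ± 874 CPM. With the monocyte and macrophage marker level (the list score, not the summed CPM) as a covariate the calls of MHC class II (adjusted p = 0.106) and interferon gamma response (adjusted p = 0.572) ended, although Ctss is in both the MHC class II and the marker list. With the B cell marker level both stayed called by the preset test (adjusted p = 0.0343 and 3.42e-05), and not with an estimated correlation (lowest adjusted p of any list 0.371). Within the 7 treated libraries the MHC class II score went with the B cell marker score (Pearson r 0.867, permutation p = 0.0129, adjusted p = 0.0258 over 4 relations, r = 0.851 without the 2 libraries farthest from the median; Spearman rho 0.821, permutation p = 0.0341, adjusted p = 0.0682). The interferon gamma call also ended without control 2 (0.139) or treated 6 (0.0619), the B cell call without control 3 (0.223), treated 3 (0.0628) or treated 4 (0.0613), and the monocyte call without control 1 (0.416), control 2 (0.966), treated 4 (0.0591), treated 5 (0.103) or treated 6 (0.256). The B cell call ended without control 3 and control 4 (0.620) and with detected genes as a covariate (0.197). The monocyte call ended without erythroid and platelet genes (0.0503) and with the length and GC correction (0.191).

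Of the signalling lists, those of TNF and NF-kB response (21 of 29 above 0, adjusted p = 0.0210, and adjusted p = 0.559 with an estimated correlation), immediate early and heat shock genes (19 of 25, adjusted p = 0.0214, and adjusted p = 0.404 with an estimated correlation), IL-5 and GM-CSF signalling (15 of 21, adjusted p = 0.0235, and adjusted p = 0.404 with an estimated correlation) and type 2 activation (14 of 16, adjusted p = 0.0323, and adjusted p = 0.419 with an estimated correlation) rose by the preset test. Csf2rb, the shared beta chain of the IL-5 and GM-CSF receptors, stood at 359 ± 82.8 CPM in treated (SD, n = 7) and 228 ± 116 CPM in control libraries (SD, n = 4). Mcl1, the other of the 2 most abundant members of that list, stood at 736 ± 237 and 662 ± 162 CPM. Its member Bcl2l1 went the other way, at 117 ± 51.7 and 583 ± 634 CPM, with 1258 CPM in control 3 and 991 CPM in control 4. Dusp1, a stress-induced phosphatase, stood at 3110 ± 1920 and 2970 ± 1430 CPM, and Alox15, a lipoxygenase, at 1320 ± 541 and 938 ± 179 CPM. The call of IL-5 and GM-CSF signalling ended without control 2 (adjusted p = 0.141), control 3 (0.0584), control 4 (0.0572) or treated 1 (0.0516), without control 3 and control 4 together (0.0882) and with the correction for length and GC content (0.096). That of TNF and NF-kB response ended without control 1 (0.450), control 2 (0.224), treated 5 (0.0688) or treated 6 (0.0532), that of immediate early and heat shock genes without control 1 (0.139) or treated 5 (0.0533), and that of type 2 activation without control 2 (0.175), control 4 (0.169), treated 3 (0.0563), treated 4 (0.0591) or treated 6 (0.0532). With the monocyte and macrophage marker level as a covariate all 4 calls ended, with adjusted p = 0.549 for TNF and NF-kB response, 0.0574 for immediate early and heat shock genes, 0.0574 for IL-5 and GM-CSF signalling and 0.240 for type 2 activation. The type 2 call also ended with the stricter filter (0.0949), without control 3 and control 4 together (0.0633) and with detected genes (0.0850) or the B cell marker level (0.0746) as a covariate. That of immediate early and heat shock genes ended with the stricter filter (0.0525), and that of TNF and NF-kB response with the length and GC correction (0.0628). Without control 3 and control 4, with 2 controls left, the median log2 fold change of type 2 activation went from 0.598 to 1.78. The median of IL-5 and GM-CSF signalling went from 0.293 to 0.491 there. The differences in list score went the other way. They fell from 0.563 to 0.45 for IL-5 and GM-CSF signalling and from 1.46 to 1.31 for type 2 activation.

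Erythroid markers fell by the preset test, with 7 of 10 lower adjusted over the list alone (adjusted p = 0.00127, and adjusted p = 0.559 with an estimated correlation), as did platelet markers (11 of 11 below 0, adjusted p = 0.0341, and adjusted p = 0.672 with an estimated correlation). Hbb-bs stood at 9520 ± 4300 CPM in treated (SD, n = 7) and 88100 ± 103000 CPM in control libraries (SD, n = 4), and the platelet chemokine Pf4 at 310 ± 167 and 1080 ± 1210 CPM. Reads of the near-identical haemoglobin genes can be assigned to either copy. Without control 3 and control 4 both lists turned to the opposite direction (adjusted p = 3.49e-18 for erythroid and 6.91e-22 for platelet markers by the preset test, and adjusted p = 0.116 for both with an estimated correlation), with the log2 fold change of Hbb-bs going from -3.21 to 2.18 and that of Pf4 from -1.80 to 2.67. With detected genes as a covariate both also turned to higher (adjusted p = 0.0189 and 0.0107 by the preset test, and adjusted p = 0.562 for both with an estimated correlation). With the B cell marker level the erythroid call ended (0.646) and platelet markers turned to higher (0.814). Without control 3 or control 4 alone the erythroid call ended (adjusted p = 0.670 and 0.228), and the platelet list turned to higher without control 3 (0.690), and its call ended without control 4 (0.915), treated 3 (0.0563), treated 4 (0.0607), treated 5 (0.0648) or treated 7 (0.0785).

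The other lists did not pass the preset test. Eosinophil identity (6 of 22 members above 0, adjusted p = 0.595) and granule proteins (1 of 8, adjusted p = 0.617) were among them. So were the type I interferon response (24 of 35, adjusted p = 0.147), MHC class I processing (16 of 21, adjusted p = 0.132) and targets of p53, the DNA damage response factor (18 of 26, adjusted p = 0.0722). In the type I interferon list, Ly6e stood at 532 ± 210 CPM in treated and 222 ± 128 CPM in control libraries. Rsad2 went the other way, at 197 ± 63.7 and 990 ± 1240 CPM, with 2634 CPM in control 3 and 1267 CPM in control 4. The unfolded protein response (13 of 18, adjusted p = 0.0595), proliferation (14 of 30, adjusted p = 0.551), migration and adhesion (16 of 27, adjusted p = 0.551) and apoptosis regulators (10 of 21, adjusted p = 0.551) did not pass either. Some of these lists gained calls in other settings, by the preset test or, with the length and GC correction, by preranked camera. The type I interferon response was called higher without control 3 (adjusted p = 0.000332), without control 3 and control 4 (1.58e-07), without treated 7 (0.0366), without the filter (0.0337) and with the length and GC correction (0.0368). It was also called with detected genes (0.00858), header letters (0.000144) or the B cell marker level (0.000900) as a covariate. It turned to lower, short of the threshold, without control 2 (0.660) or treated 6 (0.966) and with the monocyte and macrophage marker level (0.156). MHC class I processing was called higher without control 4 (0.0103), without control 3 and control 4 (0.000334), without the filter (0.0355) and with the length and GC correction (0.0368). It was also called with detected genes (0.0119) or the B cell marker level (0.0309) as a covariate. Targets of p53 were called higher without control 4 (0.0354), with either other filter (0.0171 and 0.0460), with the header letters (0.0496) and with the length and GC correction (0.0456). The unfolded protein response, migration and adhesion, and markers of neutrophils, T cells and dendritic cells each gained a call in at least 1 setting. Granule proteins were called lower without control 2 (0.0460), and higher without control 3 and control 4 (0.0375) and with the B cell marker level as a covariate (0.0309). With an estimated correlation 0 lists were called in any of these settings (lowest adjusted p = 0.107, for IL-5 and GM-CSF signalling with the header letters). It was not run with the length and GC correction. Inhibitory and costimulatory receptors (11 of 20, adjusted p = 0.677), Fc receptors (4 of 8, adjusted p = 0.922) and cytotoxic effectors (3 of 6, adjusted p = 0.221) were also short of the threshold. Of the marker lists, those of neutrophils (0 of 11, adjusted p = 0.132), T cells (2 of 7, adjusted p = 0.993) and dendritic cells (4 of 6, adjusted p = 0.158) did not pass. The median fold change and the direction of the test differed in sign for T cells (median -0.56, test higher), proliferation (median -0.04, test higher) and inhibitory and costimulatory receptors (median 0.06, test lower). The lists of NK cells, plasma cells, basophils and mast cells, and epithelial tumour cells had fewer than 5 tested members. By fry, a self-contained test, 0 lists passed, and the lowest adjusted p was 0.084 in its directional form. In its form that ignores direction the lowest was 0.0552, for the unfolded protein response.

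The summed level of each marker list did not differ between groups for any of 11 cell types by an exact two-sided permutation test (lowest adjusted p = 0.690). Monocyte and macrophage markers summed to 8600 ± 5580 CPM of the library total in treated (SD, n = 7) and 5080 ± 5790 CPM in control libraries (SD, n = 4). B cell markers summed to 3900 ± 2460 and 1880 ± 1300 CPM, and neutrophil markers to 10800 ± 3670 and 10300 ± 2550 CPM. Most of the neutrophil sum came from 1 gene, Retnlg (9270 ± 3700 and 10300 ± 4700 CPM, scaled with TMM). The neutrophil list score, the mean log2 CPM of its tested members, ran from 2.4 to 7.14 in treated and from 2.34 to 8.36 in control libraries. Without control 3 and control 4 the mean log2 difference of B cell markers went from 1.12 to 0.243, of monocyte and macrophage markers from 1.16 to 2.19, of erythroid markers from -0.429 to 2.47 and of platelet markers from 0.115 to 2.28. With 2 controls the smallest exact permutation p is 0.0278, reached by the last 2 lists (adjusted p = 0.153), so no list could pass there by itself.

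**Figure D2:**
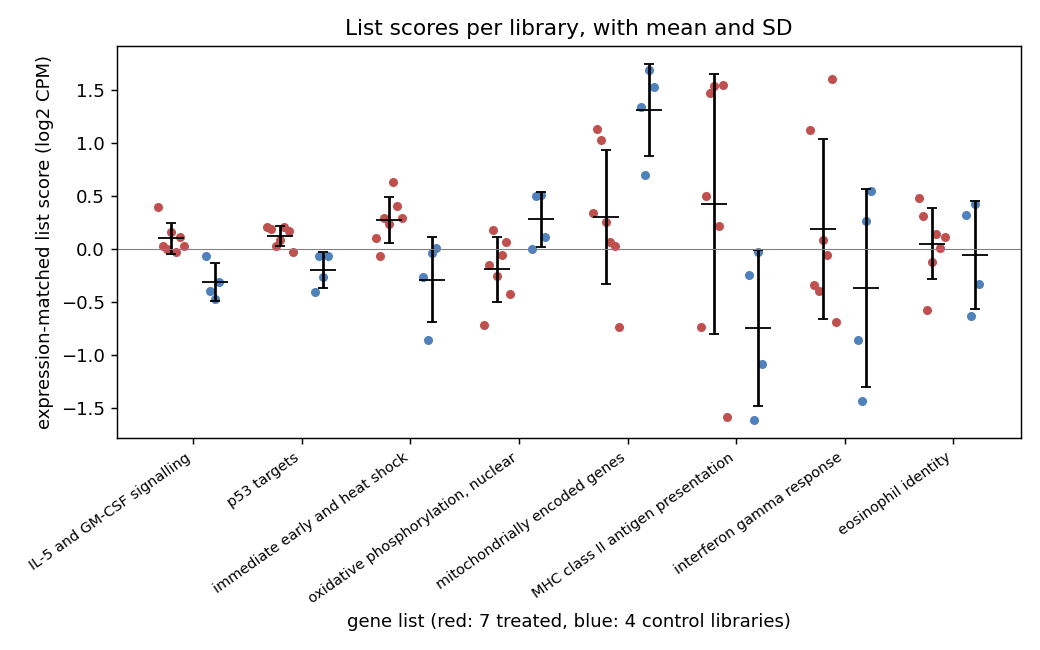
Expression-matched score (log2 CPM relative to genes of the same mean expression in the same library) of 8 gene lists, with 1 point per library, red for the 7 treated and blue for the 4 control libraries, and mean ± SD in black. The scores of IL-5 and GM-CSF signalling and of p53 targets lie above all 4 control libraries in 7 of 7 treated libraries, while those of most other lists overlap.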

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

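A library lying far from the others of its group was found 14 times among 247 groups of values examined, or 5.67%, and chance alone gives about 5%. These values are given without explanation. Among marker levels, basophil and mast cell markers summed to 491 CPM in treated 4, with the next library at 38.8 CPM. Among list scores, inhibitory and costimulatory receptors had an expression-matched score of -0.655 in control 2, with the nearest control at -0.0834.

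Among single genes in control libraries, Dusp1 stood at 898 CPM in control 3 with the nearest control at 3240 CPM, and St8sia4 at 75.4 CPM in control 2 with the nearest at 40.2 CPM. Slamf9 stood at 1.60 CPM in control 3 with the nearest at 0.141 CPM. Aldh1b1 (0.507 CPM), Kit (3.80 CPM) and Thnsl1 (0.127 CPM) were detected in control 1 and Slfn9 (0.141 CPM) in control 2, each with 0 counts in the other controls. Among treated libraries, Gbp9 stood at 28.4 CPM in treated 3 with the nearest at 104 CPM, and Lat at 0.147 CPM in treated 3 with the nearest at 10.5 CPM. Klf6 stood at 2680 CPM in treated 7 with the nearest at 1440 CPM, and Rps9 at 436 CPM in treated 4 with the nearest at 575 CPM. Ly6g stood at 15.1 CPM in treated 1 and had 0 counts in the other treated libraries.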

How the results depend on the processing

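The counts of 0 genes higher and 0 lower were the same under every edgeR and limma setting run, leave-one-out included (0 to 0), and differed with DESeq2, which called 60 and 22. The lowest adjusted p under the settings that call 0 genes was 0.0644, without control 3 and control 4. The list counts of 8 higher and 6 lower were less stable. Both were 0 with fry and 0 with an estimated correlation, also when that was run in each of the other edgeR settings except the length and GC correction (lowest adjusted p = 0.107). Every list call below rests on the preset correlation or on permutation. Leaving out 1 library gave 4 to 9 lists higher and 2 to 8 lower. Lower lists numbered 3 with detected genes as a covariate and 3 with the B cell marker level as a covariate. They also numbered 3 without erythroid and platelet genes, where the erythroid and platelet lists could not be tested. Of the other lower lists only glycolysis lost its call there (adjusted p = 0.0515 by the preset test). With the monocyte marker level as a covariate 1 list was higher. Without control 3 and control 4, 13 were higher and 2 lower. By exact permutation of list scores 3 were higher and 0 lower, and in the expression-matched form 2 higher and 0 lower. Of these settings, the removal of erythroid and platelet genes, both marker covariates, leaving out control 3 and control 4 together and both permutations were chosen after seeing the data. For all of them the cause was not tested.

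Erythroid markers turned to higher with detected genes as a covariate (adjusted p = 0.0189) and without control 3 and control 4 (adjusted p = 3.49e-18). Platelet markers turned to higher in the same settings (adjusted p = 0.0107 and 6.91e-22), with the B cell covariate (adjusted p = 0.814) and by permutation of list scores (adjusted p = 0.952), and without control 3 (adjusted p = 0.690), and over single libraries left out their adjusted p ran from 1.96e-09 to 0.915. With an estimated correlation both had adjusted p = 0.116 without control 3 and control 4, and 0.562 with detected genes as a covariate. Granule proteins turned to higher without control 3 and control 4 (adjusted p = 0.0375, and adjusted p = 0.471 with an estimated correlation) and with the B cell covariate (adjusted p = 0.0309), and were called lower without control 2 (adjusted p = 0.0460, and adjusted p = 0.657 with an estimated correlation). With the header letters as a covariate, also chosen after seeing the data, 0 genes were higher and 0 lower, and 7 lists higher and 5 lower. MHC class II (adjusted p = 0.887) and B cell markers (0.000243) turned to lower there, and glycolysis (0.417) and inhibitory and costimulatory receptors (0.0419) to higher. Replicate numbers 1 to 4 occur in both groups but name different mice, and same-numbered libraries did not deviate together (correlations -0.0315, 0.0212, -0.116 and -0.0417). With the replicate block 0 genes were higher and 0 lower, and 7 lists higher and 4 lower. Proliferation was among the higher ones there (adjusted p = 0.0284), and TNF and NF-kB response (0.142), immediate early and heat shock genes (0.205), erythroid markers (0.202) and platelet markers (0.806) were not called.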

Other observations

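The tests without control 3 and control 4, the length and GC correction, the list scores and the counts over other splits of the samples were chosen after the list results were seen. The bounds for the expression-matched score of the IL-5 list, for its relation to monocyte markers and for the macrophage and monocyte marker levels were written before those values were seen.

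By expression-matched score, p53 targets were higher in 7 of 7 treated libraries than in all 4 controls (0.12 ± 0.0942, SD, n = 7, against -0.19 ± 0.166, SD, n = 4; exact two-sided permutation p = 0.00303, the smallest that 330 splits can give, adjusted p = 0.0439 over 29 lists). IL-5 and GM-CSF signalling gave the same exact p and adjusted p (0.10 ± 0.148 against -0.31 ± 0.180). In the first form of the score, without matching, these lists and immediate early and heat shock genes had adjusted p = 0.0293, and the latter had 0.0879 once matched. The scores are 2 of the 5 forms of list test run on the same libraries, and were added after the other 3 had been seen. Neither list passed with an estimated correlation (adjusted p = 0.506 for p53 targets and 0.404 for IL-5 and GM-CSF signalling). No bounds were written for p53 targets. Their difference was 0.352 without control 3 and control 4, compared with 0.317 with all libraries. With the monocyte covariate their adjusted p was 0.0574 by camera. The lowest treated score of p53 targets was -0.0275, close to the highest control score of -0.0565. Of their 2 most abundant members, Btg2 stood at 392 ± 61.9 CPM in treated and 452 ± 128 CPM in control libraries. The other, Plk2, stood at 189 ± 72.3 and 173 ± 148 CPM.

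Chance as the source of the counts could not be excluded. Among 100 of the 330 splits into 7 and 4, the real one included, 8 gave 777 or more genes at an unadjusted p under 0.05. The real grouping gave 777 and is 1 of the 8. The other 7 gave 1054, 946, 942, 917, 862, 857 and 793. All of these but that with 942 held control 3 and control 4 together in the group of 4, as the real grouping does. High counts thus went mostly with these 2 libraries held together, although some splits that held them together gave fewer, such as 478. As many lists as the real 14 were called by the preset test in 11 of the 100 splits, the real one included, and the highest of the others was 18.

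For the higher IL-5 and GM-CSF list, the difference stayed after matching on expression (exact permutation p = 0.00303). This cannot decide on lower complexity of the control libraries, because the matching may not have removed it. Among controls the matched score was highest in control 1, with 14550 detected genes, and lowest in control 3 (-0.47), with 10775. Against this, treated 5, with 12639 genes, scored -0.03, above control 2 (-0.39), with 12945. Whether control 3 and control 4 alone carry the difference cannot be decided. It was 0.323 without them, compared with 0.408 with all libraries. The value of 0.323 rests on control 1 and control 2 only, whose scores were -0.06 and -0.39. The bound for this check was written after the list results were seen. The camera call itself ended without control 3 and control 4 (adjusted p = 0.0882). RNA of monocytes and macrophages stays open: within the 7 treated libraries the score had Spearman rho 0.143 with the marker score (permutation p = 0.783, adjusted p = 0.783 over 4 relations; Pearson r 0.140, permutation p = 0.684, adjusted p = 0.684; r = -0.0857 without the 2 libraries farthest from the median). With the monocyte covariate the adjusted p of the list was 0.0574. A possible batch that follows the groups cannot be told apart from the treatment.

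For the lower respiration lists, the length and GC trend reduced the difference of the nuclear list, whose median relative to all genes went from -0.45 to -0.209 ± 0.0992 (SE over libraries). What remained passed the bound of -0.1 by little more than 1 SE (exact permutation p = 0.0121, and 0.0212 without the correction), so the trend may account for part of the pattern, and whether it accounts for all is not clear. Without control 3 and control 4 the median was -0.516 ± 0.393, again past the bound by little more than 1 SE, and the exact permutation p with 2 controls left was 0.222. The mitochondrially encoded list, at -1.10 with all libraries, stood at -0.637 ± 0.391 with the correction (exact permutation p = 0.118) and at -0.543 ± 0.292 without control 3 and control 4 (exact permutation p = 0.222). A treatment effect, these 2 libraries, the possible batch and chance remain open.

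Several genes that DESeq2 called higher, among them Timd4, C1qb (124 ± 173 CPM in treated, SD, n = 7, and 2.75 ± 3.32 CPM in control libraries, SD, n = 4), C1qc, Prg4 and Lyz1, are known from resident macrophages of body cavities, which carry CD11b and F4/80, while the gate on high side scatter and low Ly6g selects granular cells other than neutrophils. Because these genes were picked from the calls, 14 others of such macrophages, chosen without their values being looked at, were summed, and their mean log2 level differed by 0.631 (exact two-sided permutation p = 0.0939), which neither meets nor excludes the prediction that RNA of such cells may be present, with F5 (961 ± 277 and 1030 ± 184 CPM) and Apoe, high in both groups, making up most of the sum. Within the 7 treated libraries this sum went with that of the picked genes (Pearson r 0.828, permutation p = 0.00337, adjusted p = 0.0135 over 4 relations, r = 0.902 without the 2 libraries farthest from the median; Spearman rho 0.821, permutation p = 0.0341, adjusted p = 0.0682) and had Pearson r 0.647 with the MHC class II score (permutation p = 0.106, adjusted p = 0.141, r = 0.980 without the 2 farthest; Spearman rho 0.750, permutation p = 0.0663, adjusted p = 0.0884). Of the 14, Fcna (157 ± 223 and 3.46 ± 6.83 CPM), C1qa (52.9 ± 64.2 and 4.76 ± 3.80 CPM) and Cd5l (counts in 4 of 7 treated and 0 of 4 control libraries) were singled out after their values were seen. Only F5 and Naip1 (1.56 ± 1.35 and 2.18 ± 3.20 CPM) had a lower mean in treated libraries. Icam2 differed little (96.9 ± 14.3 and 83.4 ± 28.6 CPM). Gata6 had counts in 1 of 7 treated and 0 of 4 control libraries, and Rarb in 2 and 0. Blood monocytes stay open in the same way, with a difference of 0.898 for 5 of their markers (exact permutation p = 0.285).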
